A study of Saccharomyces cerevisiae BY4741 with 24 samples.

How the data were processed

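RNA from cultures of Saccharomyces cerevisiae BY4741 in rich medium with 2% or 0.5% glucose, harvested 12, 18, 24 and 48 h after inoculation, was measured on Affymetrix Yeast Genome 2.0 arrays, per the labels with 3 biological replicates per group and 24 arrays in 8 groups. Per the labels the RNA was extracted with TRIzol and biotin-labelled cRNA was made from it. The log2 values, as deposited by the authors, were quantile normalized over all 10928 probe sets before deposition. Both facts were inferred from the values, which ranged from 0.60 to 12.57 and had the same distribution on every array, with a largest difference between sorted columns of 0.0095. Partek is named in the submitters' processing notes, with no version or role. The base of the logarithm, the background correction and the summarization of probes are not given in the sources used here, nor are array dates or batches.

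Of the probe sets 7245 had an annotation, 7244 of them with 1 gene and 1 with several, and 3683 had none. The 5498 probe sets of 1 Saccharomyces cerevisiae gene gave 5449 genes, and for the 47 genes with several probe sets the one with the highest mean was used. Symbols of 12 genes were updated to current names, and 118 genes were measured by probe sets that can be shared between related genes, HXT7 and VBA3 among them, which was not checked. The 1746 Schizosaccharomyces pombe probe sets, which no sample should contain, served as the background, with a median of 1.67 and a 95th percentile of 2.29. The 213 control and reporter probe sets were kept out of the gene tests, and 12 poly-A spike-in and 9 hybridization control probe sets were used to describe the arrays. The signal over background limits the dimmest genes, and 5396 of the 5449 genes had a group mean above the background percentile. The median SD within a group was 0.063 and the median SE of a difference between groups was 0.064.

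A linear model over the 8 groups was fitted with limma 3.58.1 in R 4.3.3, with its moderated statistics and Benjamini-Hochberg adjustment within each comparison. Genes with an adjusted p under 0.05 were counted by direction, and those that also changed by at least 2-fold were counted apart. The comparisons were 0.5% against 2% glucose at each time, their average over the 4 times, the effect at 48 h minus that at 12 h, the F test for any difference of the glucose effect between times, 48 h against 12 h within each glucose level, and the successive time steps. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The 29 gene lists held 801 members, of which 784 were measured, and were written from general knowledge of yeast before the data were examined. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with a correlation estimated from the data and the rotation test fry were the alternatives for lists.

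Genes were named by a rule. For each glucose comparison the rule took the 6 highest and the 6 lowest log2 changes among genes past the threshold, with non-overlapping arrays, a level above background and a standard name, and up to 3 members of each list by the size of the moderated statistic. For the 48 h against 12 h comparisons and the difference of effects it took 5 of each, and for all comparisons a fixed panel of 26 genes. The examples in the text are a part of the genes so named.

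The replicate numbers were checked as possible pairs. With correlations of the residuals of same-numbered arrays above 0.1 in every pair as the rule, the numbers paired at 12 h (0.212, 0.138 and 0.109), 18 h (0.307, 0.229 and 0.364) and 24 h (0.368, 0.117 and 0.360). They did not at 48 h (0.100, 0.156 and 0.072), nor for 48 h against 12 h in 2% (0.175, -0.072 and 0.271) or 0.5% glucose (0.095, 0.006 and 0.117). Of the successive steps only that from 12 h to 18 h in 2% glucose met the rule (0.456, 0.148 and 0.3). Of all 84 pairs of same-numbered arrays 41 were above 0.1, and in 54 of 84 cases an array correlated best with the array of its own number. Since the rule was not met in every comparison, the numbers were used as a block only as an alternative. The main fit thus leaves out a pairing that part of the arrays show.

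The alternatives chosen in advance were quantile normalization again over the tested probe sets, centring on the array median, removal of dim probe sets, a variance trend with robust moderation, array weights, only the arrays compared, the replicate block, the mean of a gene's probe sets, leaving out each array in turn, and both other list tests. Chosen after the data had been seen were a scale from the group means of the poly-A spike-ins, then one from the spike-ins of each array, and the average and F test without the 48 h arrays. The p-values on the group-mean scale leave out the spread of the spike-ins. For the average, the difference of effects and the change from 12 h to 48 h, only medians and directions were taken on the group-mean scale, after the other values had been seen. Splits of the arrays into other groups were counted, all 10 for 3 against 3 and 100 for the average, the difference of effects and the F test.

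The fit was tested on simulated data with 5449 genes and 50 changed genes per size. Of changes of 0.25 on the log2 scale 56%, 60%, 58% and 68% were recovered at 12, 18, 24 and 48 h, and of changes of 0.5 between 96% and 100%. False calls made up 6.8%, 3.8%, 6.3% and 2.1% of the calls, and 0 calls of changed genes by limma had the wrong sign. A list shifted by 0.2 was called in each of the 4 comparisons and 0 of the 28 other lists were called by camera. The simulated genes were drawn independently, while the estimated correlation within the ribosomal protein list was 0.571 in the real data. The list result therefore cannot tell how often camera with the preset correlation makes false calls on correlated lists. The F test recovered 177 of 200 changed genes, with 10 false calls. No genome coordinates were needed, and raw array files were not analysed here.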

Results

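The data were 24 expression arrays of Saccharomyces cerevisiae BY4741, a haploid laboratory strain of mating type a. Cultures were grown in rich medium with 2% glucose as the control or with 0.5% glucose as caloric restriction, and were harvested 12, 18, 24 and 48 h after inoculation. Each of the 8 combinations of glucose level and time had 3 arrays, described in the series design as biological triplicates. After annotation, 5449 genes were tested, of which 5396 had at least 1 group mean above the background level of 2.29, the 95th percentile of the Schizosaccharomyces pombe probe sets on the same arrays. The number of arrays limits the precision, and the median standard error of a difference between groups was 0.064 on the log2 scale. Every change is a log2 difference, given as estimate ± SE with 3 arrays per group, and is positive where the level was higher in 0.5% glucose or at the later time. The values were quantile normalized per array, so each change is relative to the other transcripts of the array. The 12 poly-A spike-in probe sets, for bacterial control transcripts, gave a different scale, on which the median of all genes was 0.35 at 12 h, 0.16 at 18 h, 0.27 at 24 h and -0.41 at 48 h. It is named the spike-in scale here, and the amounts of spike-in added are not given in the sources used here. The spike-ins themselves differed between the glucose levels by -0.402 ± 0.114, -0.16 ± 0.264, -0.267 ± 0.231 and 0.49 ± 0.165 at these times. At 18 h and 24 h this shift was within 2 SE of 0. Turns of direction on the spike-in scale at those times are thus within the spread of the spike-ins.

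The glucose level and the harvest time both separated the arrays. The 1st principal component held 58.2% of the variance between arrays, and the 3 arrays of 0.5% glucose at 48 h lay at 61.9 to 64.7 on it, while the other 21 arrays lay between -22.0 and 13.2. The 2nd component, with 15.3%, separated the glucose levels, with the 12 arrays of 0.5% glucose at 5.08 to 19.8 and the 12 arrays of 2% glucose at -18.2 to -2.30. The glucose effect differed between times for 4997 of 5449 genes (91.7%) by limma's F test. Without the 48 h arrays, a choice made after the data had been seen, it differed for 3852 genes.

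**Figure D1:**
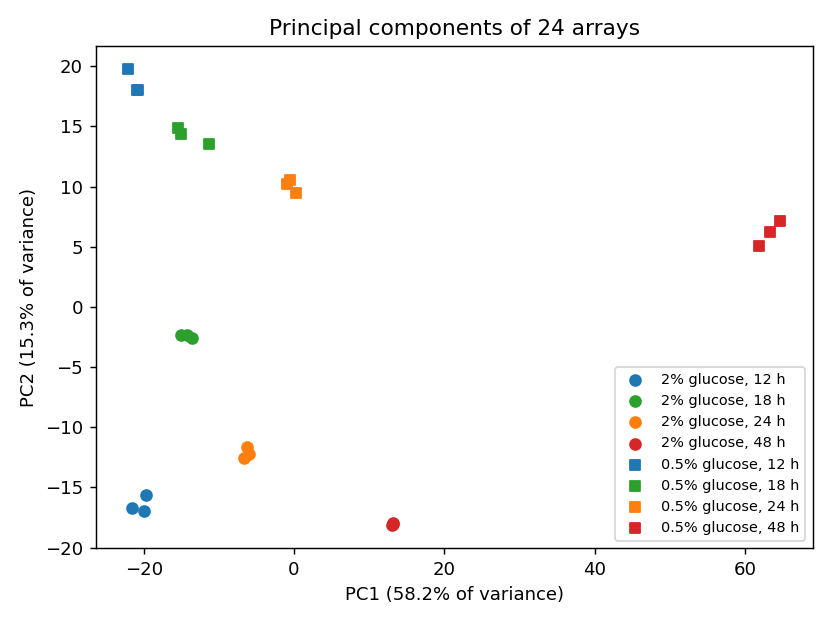
Scores of the 24 arrays on the first components of variation across 5449 genes, one point per array, coloured by hours after inoculation, with circles for 2% and squares for 0.5% glucose. The axes are component scores, with the percentage of variance on each axis label (58.2% and 15.3%), and the 3 arrays of 0.5% glucose at 48 h lie at 61.9 to 64.7 on the 1st axis.

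The series design names 12 h as about the time from which restricted cells had the potential for a longer chronological lifespan, so the first comparison was that of the glucose levels at 12 h. Genes for the cytosolic ribosome were higher in 0.5% glucose at this time: 127 of the 128 measured, 107 of them by at least 2-fold, with a list median of 1.48. Their median level was low in 2% glucose at 12 h, at 8.10, against 9.20, 9.065 and 9.19 at 18, 24 and 48 h. In 0.5% glucose it was 9.70, 9.61, 9.61 and 9.88 at the 4 times. RPL24A was 5.31-fold higher (2.41 ± 0.06), RPL5 was 3.79-fold higher (1.92 ± 0.05), and RPL3 changed by 1.54 ± 0.05. Heat shock proteins and chaperones, which assist protein folding, were lower in 24 of 25 members, with a median of -0.74, led by SSA4 (-2.22 ± 0.06) and HSP82 (-1.68 ± 0.07). All 7 a-specific genes, which mating type a cells express for mating, were lower, with a median of -2.23, and the a-factor gene MFA1 (YDR461W) was 9.24-fold lower (-3.21 ± 0.06). For the ribosomal proteins camera gave an adjusted p of 1.3e-47, and adjusted p = 0.108 with an estimated correlation. For the chaperones these were 1.1e-08 and adjusted p = 0.0769 with an estimated correlation, and for the a-specific genes 2.76e-06 and adjusted p = 0.0858 with an estimated correlation.

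Other genes with the largest differences at 12 h included ALP1 (YNL270C), for an amino acid permease, at 10.6-fold higher (3.40 ± 0.07), and FDH1 (YOR388C), for formate dehydrogenase, at 7.24-fold higher (2.86 ± 0.13). AGA1, for the anchor of a cell adhesion protein used in mating, was lower by 6.96-fold (-2.80 ± 0.09), and CYC7, for an isoform of cytochrome c, by 6.90-fold (-2.79 ± 0.08). URA1, for dihydroorotate dehydrogenase of pyrimidine synthesis, was lower by 6.35-fold (-2.67 ± 0.05), and HXT4, for a glucose transporter, by 6.34-fold (-2.66 ± 0.10). Among the regulators, MSN4, for an activator of stress genes, fell by 1.28 and HAP4, for an activator of respiratory genes, fell by 0.62.

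Of the other lists, 7 with a higher direction at 12 h passed camera, as follows. Of 83 genes for ribosome biogenesis 66 were higher and 4 lower, with a median of 0.54 and NOP1 at 1.86 ± 0.09 (adjusted p = 5.24e-10, and adjusted p = 0.302 with an estimated correlation). Of 33 DNA replication genes 32 were higher and 1 lower, with a median of 0.52 and POL1, for the catalytic subunit of the primase-associated polymerase, at 1.11 ± 0.06. Camera gave this list an adjusted p of 4.61e-08, and adjusted p = 0.143 with an estimated correlation. Cyclins and mitosis genes were higher in 13 of 17 members and lower in 2, with CLN1 at 1.54 ± 0.07 (adjusted p = 0.000484, and adjusted p = 0.0769 with an estimated correlation). Histone genes were higher in 7 of 9, with a median of 0.35 (adjusted p = 0.0126, and adjusted p = 0.302 with an estimated correlation). Amino acid biosynthesis genes were higher in 37 of 52 and lower in 11, with ASN2 at 1.58 ± 0.05 (adjusted p = 5.57e-06, and adjusted p = 0.143 with an estimated correlation). Ergosterol genes, for the yeast sterol pathway, were higher in 15 of 23 and lower in 5, with ERG6 at 1.84 ± 0.06 (adjusted p = 0.00187, and adjusted p = 0.377 with an estimated correlation). The iron regulon, which serves iron uptake, was higher in 11 of 16 and lower in 5, with TIS11 at 1.94 ± 0.06 and FRE2 at -1.43 ± 0.07. The list had an adjusted p of 0.0185, and adjusted p = 0.302 with an estimated correlation.

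The lists of carbon metabolism that passed at 12 h differed in direction. Of 18 genes for the glyoxylate cycle, gluconeogenesis and the use of 2-carbon compounds, 11 were higher and 2 lower, with ADH2, for the alcohol dehydrogenase that oxidizes ethanol, at 1.67 ± 0.05 and ICL1, for isocitrate lyase, at 1.22 ± 0.05. By camera the adjusted p was 0.00145, and adjusted p = 0.108 with an estimated correlation. Of 20 glycolysis and fermentation genes 15 were higher and 3 lower, with ENO2 at 1.28 ± 0.06 and HXK1 at -1.12 ± 0.05 (adjusted p = 0.00367, and adjusted p = 0.302 with an estimated correlation). Trehalose and glycogen genes, for storage carbohydrates, were lower in 14 of 20 and higher in 3, with a median of -0.43 that was -0.03 on the spike-in scale, NTH2 at -0.88 ± 0.05 and PGM1 at 1.25 ± 0.08. For this list camera gave an adjusted p of 0.00433, and adjusted p = 0.302 with an estimated correlation. Hexose transporters and sensors were lower in 7 of 11 with a median of -0.53 and did not pass (adjusted p = 0.0591). Without replicate 3 of 2% glucose at 12 h that value was 0.0451, within a range of 0.0451 to 0.0949 over 14 settings.

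A further 4 lists passed camera with a lower direction at 12 h, and the medians of 3 of them turned on the spike-in scale. Oxidative stress defence genes were lower in 20 of 25 and higher in 4, with a median of -0.39 that turned to 0.02 on the spike-in scale, and TSA2, for a peroxiredoxin, was -1.08 ± 0.07. Camera gave this list an adjusted p of 0.00145, and adjusted p = 0.298 with an estimated correlation. Autophagy genes were lower in 21 of 29 and higher in 3, with a median of -0.30 that turned to 0.10 on the spike-in scale. The list had an adjusted p of 0.00613, and adjusted p = 0.174 with an estimated correlation. Proteasome genes were lower in 26 of 33 and higher in 1, with a median of -0.25 that turned to 0.15 on the spike-in scale. By camera the adjusted p was 0.00145, and adjusted p = 0.309 with an estimated correlation. Nutrient signalling and longevity regulators were lower in 15 of 21 and higher in 2, with a median of -0.41 that was -0.004 on the spike-in scale. For this list camera gave an adjusted p of 0.0114, and adjusted p = 0.174 with an estimated correlation. Mitochondrial ribosome genes were lower in 33 of 64 and higher in 6, with a median of -0.15 that turned to 0.25 on the spike-in scale, and did not pass (adjusted p = 0.0544). That adjusted p was 0.0492 with the replicate number as a block, 0.0370 with only the 6 arrays compared, 0.0406 and 0.0451 without replicate 2 and 3 of 2% glucose at 12 h, and 0.0268 without replicate 1 of 0.5% glucose, within a range of 0.0268 to 0.0966 over 14 settings.

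At 12 h 1755 genes were higher and 2245 lower in 0.5% glucose, of which 304 and 155 by at least 2-fold. The 3 arrays of one glucose level did not overlap those of the other for 72.5% of genes, where chance gives 10% for 3 against 3. On the spike-in scale the counts were 3776 higher and 633 lower with group means, and 1966 higher and 195 lower with the spike-ins of each array. The other lists did not pass camera, and their adjusted p was 0.290 for the TCA cycle, 0.363 for the respiratory chain and ATP synthase, 0.101 for beta-oxidation, 0.0807 for RNA polymerase I and III, 0.137 for vacuolar hydrolases, 0.106 for stationary phase genes and 0.290 for the phosphate regulon. Adjusted over the list alone, 128 ribosomal protein genes, 16 glycolysis genes, 22 lower autophagy genes, 27 lower proteasome genes and 31 lower mitochondrial ribosome genes passed, and the counts of the other lists given here with their members were the same.

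**Figure D2:**
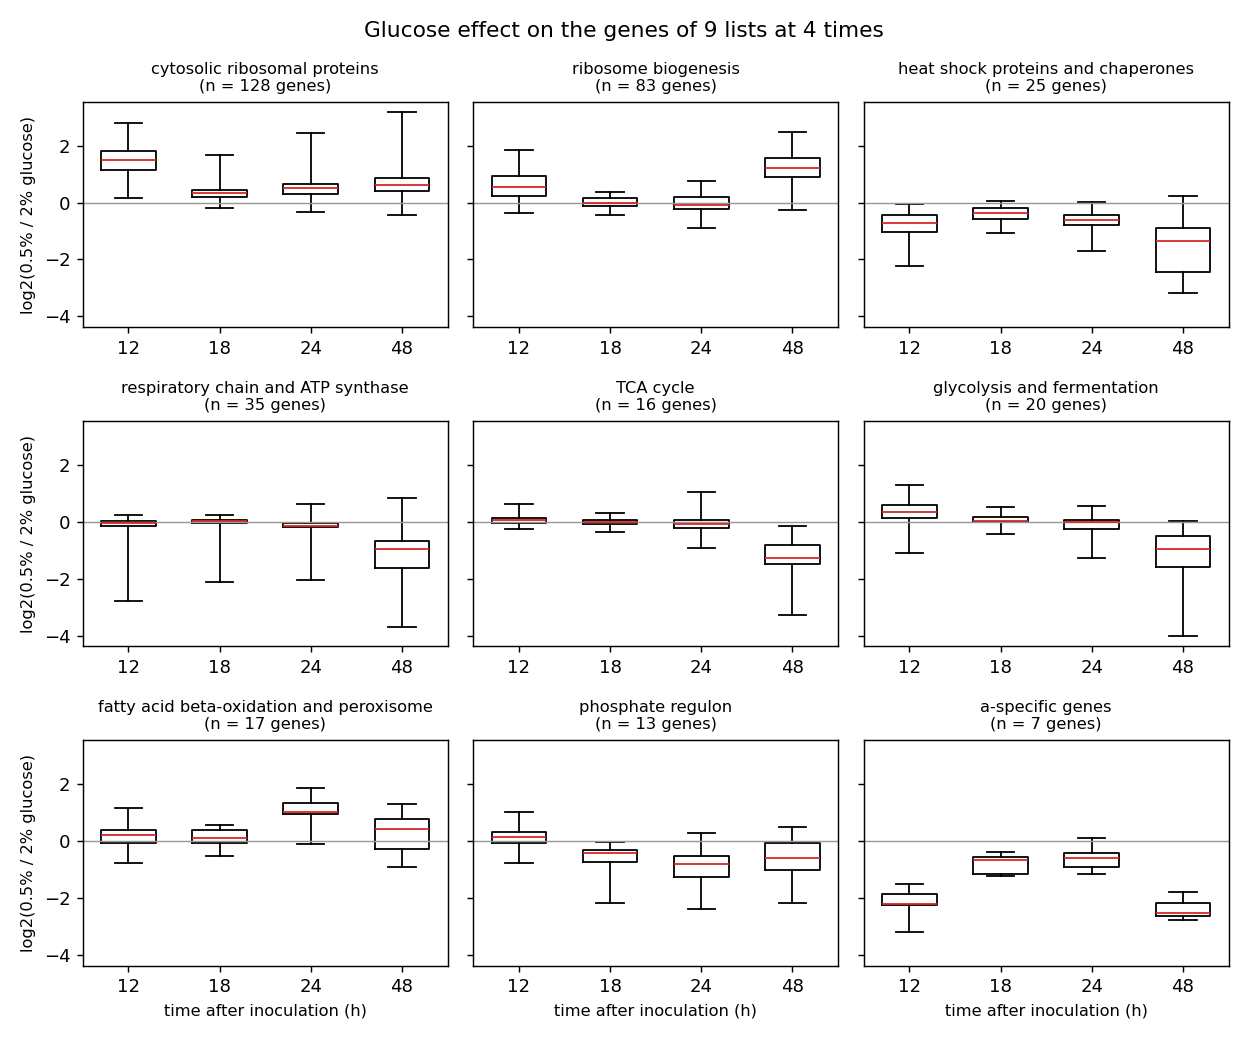
Log2 difference between 0.5% and 2% glucose for the members of 9 gene lists at 12, 18, 24 and 48 h, with boxes at the quartiles, a red line at the median and whiskers to the extreme members. The median of the ribosomal protein list was 1.48 at 12 h and 0.60 at 48 h and that of the respiratory chain list -0.06 at 12 h and -0.97 at 48 h, and on the spike-in scale the respiratory chain list turned to 0.34 at 12 h and 0.13 at 24 h, the TCA cycle to 0.16 at 18 h and 0.18 at 24 h, ribosome biogenesis to 0.15 and 0.20 at these times, glycolysis to 0.26 at 24 h, and beta-oxidation to -0.06 at 48 h. At 18 h and 24 h the shift of the spike-ins was within 2 SE of 0.

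At 18 h the glucose levels differed by smaller amounts. SAM1 (YLR180W), for an S-adenosylmethionine synthetase, was 7.44-fold higher in 0.5% glucose (2.89 ± 0.11), and the uridine permease gene FUI1 (-1.79 ± 0.08) and URA1 (-2.61 ± 0.05) were lower. The phosphate regulon, which serves phosphate uptake and storage, was lower in 11 of 13 members and higher in 0, with a median of -0.44. PHO5 (YBR093C), for a secreted acid phosphatase, was 4.57-fold lower (-2.19 ± 0.06), and PHO84, for a phosphate transporter, was -1.11 ± 0.07. This list passed camera with adjusted p = 3.69e-08, and adjusted p = 0.0221 with an estimated correlation.

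Ribosomal protein genes were higher at 18 h in 104 of 128 and lower in 1, with a median of 0.32 and RPL9A at 1.05 ± 0.06. Camera gave this list an adjusted p of 9.1e-19, and adjusted p = 0.588 with an estimated correlation. Mitochondrial ribosome genes were higher in 37 of 64 and lower in 2, with RSM19 at 0.66 ± 0.06 (adjusted p = 8.58e-05, and adjusted p = 0.902 with an estimated correlation). The iron regulon was higher in 11 of 16 and lower in 3, with TIS11 at 1.38 ± 0.06 and FIT2 at 1.13 ± 0.08. The list had an adjusted p of 0.000333, and adjusted p = 0.249 with an estimated correlation. Chaperones were lower in 20 of 25, with HSP82 at -1.06 ± 0.07 (adjusted p = 3.69e-08, and adjusted p = 0.0523 with an estimated correlation). All 7 a-specific genes were lower, with STE2, for the alpha-factor receptor, at -1.25 ± 0.06 (adjusted p = 3.99e-07, and adjusted p = 0.0523 with an estimated correlation). Genes for the glyoxylate cycle, gluconeogenesis and 2-carbon use were lower in 10 of 18 and higher in 2, with a median of -0.15 that turned to 0.01 on the spike-in scale. By camera the adjusted p was 0.0380, and adjusted p = 0.396 with an estimated correlation. Their adjusted p was 0.0659 with array weights, 0.0602 with only the 6 arrays compared and 0.0745 without replicate 1 of 0.5% glucose, within a range of 0.0161 to 0.0745 over 14 settings. Histone genes were higher in 6 of 9 and lower in 1 and did not pass (adjusted p = 0.0935), while without replicate 1 of 0.5% glucose their adjusted p was 0.0431, within a range of 0.0431 to 0.143 over 14 settings.

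At 18 h 1388 genes were higher and 1353 lower, of which 24 and 39 by at least 2-fold, and arrays did not overlap for 56.9% of genes, where chance gives 10%. On the spike-in scale the counts were 2802 higher and 579 lower with group means, and 187 higher and 59 lower with the spike-ins of each array. Ribosome biogenesis genes were higher in 7 of 83 and lower in 14, with a median of -0.01 that turned to 0.15 on the spike-in scale (adjusted p = 0.889). Adjusted over the list alone, 105 ribosomal protein genes, 39 higher and 3 lower mitochondrial ribosome genes, 12 higher iron regulon genes, 21 lower chaperone genes, 6 higher and 2 lower histone genes, and 3 higher and 6 lower ribosome biogenesis genes passed.

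At 24 h genes for fatty acid beta-oxidation and the peroxisome, the organelle that degrades fatty acids in yeast, were higher in 13 of 17 members, 10 of them by at least 2-fold, with a median of 1.02. POX1 (YGL205W), for acyl-CoA oxidase, was 3.61-fold higher (1.85 ± 0.07), and CTA1, for the peroxisomal catalase, was 1.41 ± 0.06. The list gave adjusted p = 2.38e-08, and adjusted p = 0.107 with an estimated correlation. The phosphate regulon was lower in 12 of 13 and higher in 1, with a median of -0.83 and PHO5 at -2.39 ± 0.06, and chaperones were lower in 22 of 25, with a median of -0.60 and SSA2 at -1.71 ± 0.09. Both lists also passed with an estimated correlation, with adjusted p = 0.0206 for each, beside 3.21e-07 and 1.14e-10 with the preset correlation.

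ALP1 (3.25 ± 0.07) and FDH1 (3.13 ± 0.13) had the highest changes among the genes named at 24 h, and PDR12 (YPL058C), for a transporter that exports weak organic acids, was 7.47-fold lower (-2.90 ± 0.10). URA2, for the first enzyme of pyrimidine synthesis, was -2.25 ± 0.06, and HXK2, for the main hexokinase, was -1.29 ± 0.07. Ribosomal protein genes were higher in 112 of 128 and lower in 2 (adjusted p = 2.98e-20, and adjusted p = 0.394 with an estimated correlation). The glyoxylate cycle and gluconeogenesis list was higher in 9 of 18 and lower in 2, with ADH2 at 1.34 ± 0.05 and FBP1, for fructose-1,6-bisphosphatase, at 0.55 ± 0.04. For this list camera gave an adjusted p of 0.00713, and adjusted p = 0.231 with an estimated correlation. Respiratory chain and ATP synthase genes were lower in 21 of 35 and higher in 2, with a median of -0.14 that turned to 0.13 on the spike-in scale. Camera gave this list an adjusted p of 0.00799, and adjusted p = 0.336 with an estimated correlation. Trehalose and glycogen genes were lower in 13 of 20 and higher in 2, with a median of -0.315 that was -0.05 on the spike-in scale and GPH1, for glycogen phosphorylase, at -0.70 ± 0.05 (adjusted p = 0.00168, and adjusted p = 0.336 with an estimated correlation). Of the 7 a-specific genes 6 were lower, with STE2 at -1.16 ± 0.06 (adjusted p = 0.00312, and adjusted p = 0.336 with an estimated correlation).

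At 24 h 1723 genes were higher and 1712 lower, of which 81 and 93 by at least 2-fold, and arrays did not overlap for 70.4% of genes, where chance gives 10%. On the spike-in scale the counts were 3499 higher and 673 lower with group means, and 1065 higher and 150 lower with the spike-ins of each array. Adjusted over the list alone, the ribosomal protein list had 112 higher and 3 lower genes and the respiratory chain list 2 higher and 22 lower, and the counts of the other lists given for 24 h were the same. Control probe sets differed at 24 h as well: of 7 genes with 3′ and 5′ control probe sets, 3 had a smaller 3′ excess in 0.5% glucose by over 2 SE, RIP1 (-0.24), WBP1 (-0.36) and SRB4 (-0.51), and none a larger one, and these were named after their values were seen. The TDH1 difference between 3′ and middle probe sets was lower by 2.66 SE, and the 18S rRNA reading in 0.5% minus that in 2% glucose was -2.11.

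At 48 h, up to which the series design describes a growing longevity potential, the differences were larger. Genes of the respiratory chain and ATP synthase were lower in 0.5% glucose in 33 of 35 members and higher in 1, with a median of -0.97. CYC1 (YJR048W), for cytochrome c, was 13.0-fold lower (-3.70 ± 0.07). All 16 TCA cycle genes were lower, with a median of -1.26 and SDH3, for a subunit of succinate dehydrogenase, at -3.29 ± 0.06. Of 20 glycolysis and fermentation genes 19 were lower and 0 higher, with ENO2 (YHR174W), for enolase, 16.3-fold lower (-4.02 ± 0.06) and HXK2 at -3.91 ± 0.07. In contrast, 80 of 83 ribosome biogenesis genes were higher and 3 lower, 57 of them higher by at least 2-fold, with a median of 1.22 and IMP3 at 2.18 ± 0.09. Camera gave adjusted p = 4.96e-12 for the respiratory chain, and adjusted p = 0.0113 with an estimated correlation. For the TCA cycle the values were 2.69e-08 and adjusted p = 0.0643 with an estimated correlation, for glycolysis 2.21e-07 and adjusted p = 0.130 with an estimated correlation, and for ribosome biogenesis 1.57e-12 and adjusted p = 0.234 with an estimated correlation.

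Control probe sets moved together with these groups at 48 h. The difference between the 3′ and 5′ probe sets of ACT1, a sign of transcript length, was 1.48 in 0.5% and 0.82 in 2% glucose, and that between the 3′ and middle probe sets of TDH1 was 2.46 against 0.87. The 3′ and 5′ probe sets of TDH1 differed by less, 0.31 against -0.02. Of 7 genes with 3′ and 5′ control probe sets, 4 had a larger 3′ excess in 0.5% glucose by over 2 SE and 2 a smaller one, where 2 had a larger one at 12 h, and 1 a larger and 1 a smaller one at 18 h. The probe set for the 3′ part of the 18S rRNA read 9.37 against 7.07, and the poly-A spike-ins averaged 4.85 against 4.36. A probe set for the middle part of the 25S rRNA differed less, at 11.38 against 11.04 (SD 0.181 and 0.316). The 18S rRNA reading in 0.5% minus that in 2% glucose was -1.22 at 18 h.

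Among the genes named at 48 h SRL4 (YPL033C) had the highest change, at 30.8-fold higher (4.95 ± 0.09), followed by RPS14B (3.18 ± 0.09). PDR12 was 37.6-fold lower (-5.23 ± 0.10), GND1 (YHR183W), for 6-phosphogluconate dehydrogenase, 25.5-fold lower (-4.67 ± 0.10), and URA1 16.2-fold lower (-4.02 ± 0.05). Chaperones were lower in 23 of 25 and higher in 1, with a median of -1.36 and SSA1 at -2.66 ± 0.05 (adjusted p = 3.11e-09, and adjusted p = 0.0378 with an estimated correlation). Ergosterol genes were lower in 19 of 23 and higher in 2, with ERG13 at -1.94 ± 0.04 (adjusted p = 9.2e-06, and adjusted p = 0.234 with an estimated correlation). Proteasome genes were lower in 28 of 33 and higher in 3, with PRE7 at -1.51 ± 0.04 (adjusted p = 2.92e-06, and adjusted p = 0.234 with an estimated correlation). Trehalose and glycogen genes were lower in 14 of 20 and higher in 3, with GPH1 at -3.78 ± 0.05 (adjusted p = 0.00108, and adjusted p = 0.234 with an estimated correlation). The glyoxylate cycle and gluconeogenesis list was lower in 11 of 18 and higher in 5, with ACH1, for an acetate-forming coenzyme A transferase, at -2.78 ± 0.04. The list had an adjusted p of 0.0317, and adjusted p = 0.234 with an estimated correlation. The phosphate regulon was lower in 9 of 13 and higher in 2 (adjusted p = 0.0222, and adjusted p = 0.234 with an estimated correlation). All 7 a-specific genes were lower, with a median of -2.53 and STE6, for the a-factor exporter, at -2.53 ± 0.06 (adjusted p = 2.09e-05, and adjusted p = 0.122 with an estimated correlation).

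Ribosomal protein genes were higher at 48 h in 118 of 128 and lower in 2, with a median of 0.60 that was 0.11 on the spike-in scale. By camera the adjusted p was 5.26e-12, and adjusted p = 0.425 with an estimated correlation. Of 20 genes for RNA polymerase I and III, which transcribe ribosomal and transfer RNA genes, 19 were higher, with RPA43 at 1.95 ± 0.09. For this list camera gave an adjusted p of 4.16e-05, and adjusted p = 0.170 with an estimated correlation. Histone genes were higher in 7 of 9 and lower in 1, with HTA1 at 1.43 ± 0.06 (adjusted p = 0.0317, and adjusted p = 0.412 with an estimated correlation). With the mean of all probe sets of a gene the histone value was 0.0659, within a range of 0.0234 to 0.0659 over 14 settings. Autophagy genes were higher in 21 of 29 and lower in 4, with a median of 0.45 that turned to -0.04 on the spike-in scale and ATG11 at 1.36 ± 0.06. Camera gave this list an adjusted p of 0.0182, and adjusted p = 0.234 with an estimated correlation. Mitochondrial ribosome genes were lower in 35 of 64 and higher in 15 (adjusted p = 0.0411, and adjusted p = 0.765 with an estimated correlation). Their adjusted p was 0.0692 without replicate 1 of 2% glucose and 0.0679 without replicate 2 of 0.5% glucose, within a range of 0.0215 to 0.0692 over 14 settings. Of 17 stationary phase genes 9 were higher and 5 lower (adjusted p = 0.816), with a median of 0.27 that turned to -0.22 on the spike-in scale, a mean of -0.12 and fry in the downward direction. Hexose transporters had a median of 0.02 that turned to -0.47 on the spike-in scale and a mean of -0.58, and vacuolar hydrolases 0.02, turning to -0.47, and -0.28, and neither list passed camera, whose direction was down for both (adjusted p = 0.282 and 0.523). MSN4 was -2.75 ± 0.07 and HAP4 -1.98 ± 0.07, while MSN2, for the paralog of MSN4, was 1.27 ± 0.05 and SCH9, for a growth kinase, 0.52 ± 0.06.

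At 48 h 2506 genes were higher and 2062 lower, of which 475 and 580 by at least 2-fold, and arrays did not overlap for 85.1% of genes, where chance gives 10%. On the spike-in scale the counts were 1055 higher and 3562 lower with group means, and 516 higher and 2493 lower with the spike-ins of each array. Adjusted over the list alone, 29 proteasome genes were lower, and the counts of the other lists given for 48 h were the same.

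Averaged over the 4 times, all 128 ribosomal protein genes were higher in 0.5% glucose, with a median of 0.73, and 24 of 25 chaperones and all 7 a-specific genes were lower, the chaperones with a median of -0.80. Camera gave adjusted p = 3.34e-32 for the ribosomal proteins, and adjusted p = 0.197 with an estimated correlation. It gave 5.64e-12 for the chaperones, and adjusted p = 0.0184 with an estimated correlation, and 3.85e-06 for the a-specific genes, and adjusted p = 0.0970 with an estimated correlation. Ribosome biogenesis genes were higher in 77 of 83 and lower in 0 (adjusted p = 5.64e-12, and adjusted p = 0.297 with an estimated correlation). Beta-oxidation genes were higher in 12 of 17 (adjusted p = 0.00108, and adjusted p = 0.297 with an estimated correlation), and the phosphate regulon was lower in 11 of 13. The phosphate regulon had an adjusted p of 0.000362, and adjusted p = 0.111 with an estimated correlation. Respiratory chain genes were lower in 33 of 35 (adjusted p = 1.46e-09, and adjusted p = 0.0184 with an estimated correlation), and without the 48 h arrays the adjusted p was 0.129. Genes for RNA polymerase I and III were higher in 13 of 20 and lower in 3 (adjusted p = 0.0397, and adjusted p = 0.492 with an estimated correlation), with 0.891 without the 48 h arrays and 0.0504 without replicate 1 of 0.5% glucose at 18 h, within a range of 0.0248 to 0.0504 over the other 31 settings. Amino acid biosynthesis genes were higher in 32 of 52 and lower in 14 (adjusted p = 0.0427, and adjusted p = 0.555 with an estimated correlation). Their value was 0.0541 and 0.0519 without replicate 2 and 3 of 2% glucose at 12 h, 0.0502 without replicate 2 of 2% glucose at 18 h and 0.0511 without replicate 1 of 0.5% glucose at 18 h, within a range of 0.0287 to 0.0541 over 31 settings. The glyoxylate cycle list had a median of -0.08 (0 on the spike-in scale) and a mean of 0.01 (adjusted p = 0.672), and camera and fry gave opposite directions. Stationary phase genes had a median of 0.055 and a mean of -0.03 (adjusted p = 0.901), with camera upward and fry downward. In all, 2235 genes were higher and 2128 lower, of which 38 and 88 by at least 2-fold. Adjusted over the list alone, 78 ribosome biogenesis genes were higher, and the counts of the other lists given for the average were the same.

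The glucose effect at 48 h was set against that at 12 h to test the difference itself. All 20 glycolysis and fermentation genes had a lower effect at 48 h than at 12 h, with a median of -1.10 and ENO2 at -5.30 ± 0.09. By camera the adjusted p was 1.72e-08, and adjusted p = 0.0969 with an estimated correlation. The respiratory chain list was lower in 30 of 35 and higher in 3 (adjusted p = 1.17e-08, and adjusted p = 0.0489 with an estimated correlation). The TCA cycle list was lower in 15 of 16 (adjusted p = 7.42e-08, and adjusted p = 0.0745 with an estimated correlation). Ribosomal protein genes were lower in 112 of 128 and higher in 7, with a median of -0.86 (adjusted p = 4.97e-14, and adjusted p = 0.396 with an estimated correlation). The difference of effects was 0.89 ± 0.20 for the spike-ins themselves, so that the median of all genes was 0.09 as measured and -0.80 on the spike-in scale. Ribosome biogenesis genes were higher in 56 of 83 and lower in 10, with a median of 0.65 that turned to -0.245 on the spike-in scale (adjusted p = 0.000711, and adjusted p = 0.656 with an estimated correlation). Autophagy genes were higher in 25 of 29 and lower in 4, with a median of 0.69 that turned to -0.20 on that scale and ATG8 at 0.86 ± 0.07, which turned to -0.03 (adjusted p = 0.000711, and adjusted p = 0.112 with an estimated correlation). In all, 2385 genes had a higher effect at 48 h than at 12 h and 1968 a lower one, of which 654 and 748 by at least 2-fold. Of those with a higher effect, 1574 turned to a lower one on the spike-in scale and 0 turned the other way, in direction alone and with no test. Across genes, which are not independent replicates, the glucose effects correlated at r = 0.53 between 12 and 18 h, 0.76 between 18 and 24 h, 0.38 between 24 and 48 h and 0.15 between 12 and 48 h.

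**Figure D3:**
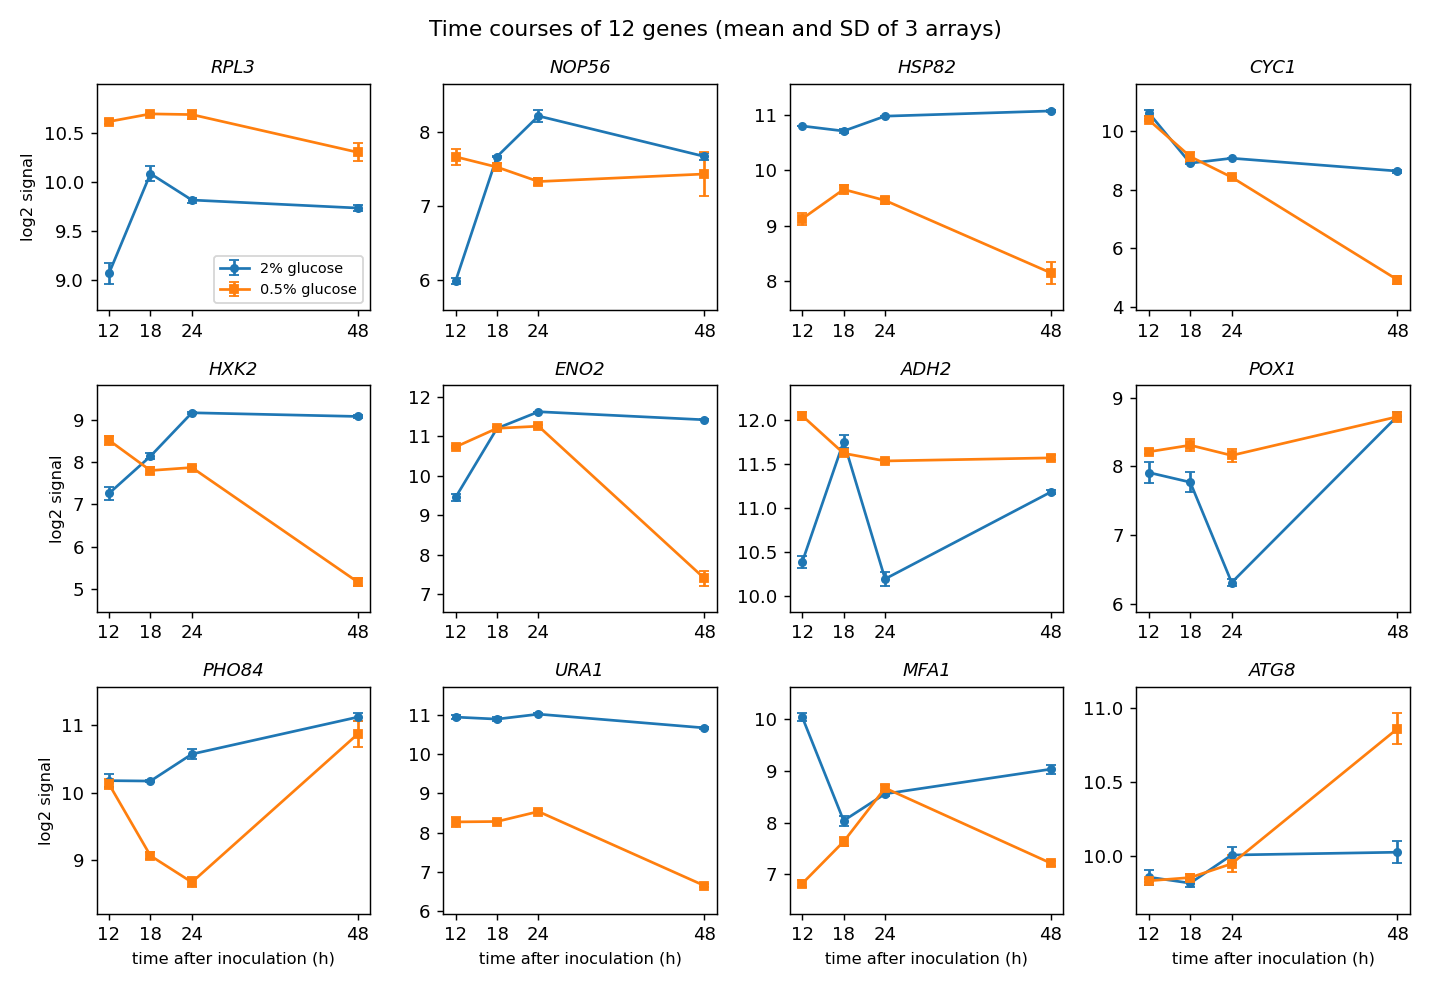
Mean log2 level and SD of 3 arrays for 12 genes against hours after inoculation, in 2% and 0.5% glucose. From 12 h to 48 h CYC1 changed by -1.98 in 2% glucose and by -5.44 in 0.5% glucose, while HXK2 changed by 1.82 in 2% and by -3.35 in 0.5% glucose.

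The change from 12 h to 48 h was then taken within each glucose level, to describe the course of control and of restricted cultures. The spike-ins themselves changed by 0.08 ± 0.13 in 2% and by 0.975 ± 0.15 in 0.5% glucose, so that the median of all genes on their scale was -0.11 and -0.90. In 2% glucose NCA3 (5.51 ± 0.12), FDH1 (4.94 ± 0.13) and DAL80 (4.38 ± 0.12), for a repressor of nitrogen catabolism, had the highest changes among the genes named, and DSE2, for a cell wall protein of daughter cells, was -2.93 ± 0.07. Mitochondrial ribosome genes were lower at 48 h in 60 of 64, with a median of -0.93 (adjusted p = 1.04e-14, and adjusted p = 0.305 with an estimated correlation). Respiratory chain genes were lower in 31 of 35 and higher in 1, with a median of -0.345 (adjusted p = 8.34e-06, and adjusted p = 0.256 with an estimated correlation). TCA cycle genes were lower in 15 of 16 and higher in 1, with a median of -0.42 (adjusted p = 0.00181, and adjusted p = 0.305 with an estimated correlation). Ribosome biogenesis genes were higher in 67 of 83 and lower in 3, with a median of 0.68 (adjusted p = 2.14e-09, and adjusted p = 0.428 with an estimated correlation). Ribosomal protein genes were higher in 125 of 128 and lower in 2, with a median of 1.04 (adjusted p = 1.14e-26, and adjusted p = 0.305 with an estimated correlation). Glycolysis genes were higher in 15 of 20 and lower in 3 (adjusted p = 0.00294, and adjusted p = 0.428 with an estimated correlation). All 4 alpha-specific genes, which mating type alpha cells express, were higher, with a median of 1.18 (adjusted p = 0.0322, and adjusted p = 0.305 with an estimated correlation). Of these, MF(ALPHA)1 (2.04) and MF(ALPHA)2 (1.91) lay below the background of 2.29 in 2% glucose at 12 h, so their changes start from the background (named after their values were seen). Amino acid biosynthesis genes did not pass (adjusted p = 0.0781), with 0.0347 under array weights and 0.0330 without replicate 1 of 2% glucose at 12 h, within a range of 0.0330 to 0.103 over 14 settings.

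In 0.5% glucose SRL4 (5.53 ± 0.09) and DAL80 (4.47 ± 0.12) had the highest changes among the genes named from 12 h to 48 h. YHB1, for a flavohemoglobin that removes nitric oxide, was -6.00 ± 0.06, CYC1 -5.44 ± 0.07, and ACS2, for an acetyl-CoA synthetase, -5.04 ± 0.07. Mitochondrial ribosome genes were lower in 58 of 64 and higher in 3, with a median of -0.94 (adjusted p = 2.68e-09, and adjusted p = 0.315 with an estimated correlation). Respiratory chain genes were lower in 33 of 35 and higher in 1, with a median of -1.16 (adjusted p = 1.3e-09, and adjusted p = 0.0314 with an estimated correlation). TCA cycle genes were lower in 15 of 16, with a median of -1.77 (adjusted p = 5.21e-07, and adjusted p = 0.132 with an estimated correlation). Glycolysis genes were lower in 17 of 20 and higher in 2, with a median of -0.735 (adjusted p = 0.000682, and adjusted p = 0.315 with an estimated correlation). Ergosterol genes were lower in 20 of 23 and higher in 2, with a median of -1.72 (adjusted p = 1.99e-05, and adjusted p = 0.315 with an estimated correlation). Cyclins and mitosis genes were lower in 14 of 17 and higher in 2, with a median of -1.59 (adjusted p = 0.00347, and adjusted p = 0.132 with an estimated correlation). Ribosome biogenesis genes were higher in 77 of 83 and lower in 3, with a median of 1.37 that was 0.40 on the spike-in scale (adjusted p = 1.3e-09, and adjusted p = 0.315 with an estimated correlation). Ribosomal protein genes were higher in 71 of 128 and lower in 32, with a median of 0.20 that turned to -0.77 on that scale, and did not pass (adjusted p = 0.128), with 0.0391 under array weights, within a range of 0.0391 to 0.211 over 14 settings. Of the stationary phase genes SNZ1, for vitamin B6 synthesis, was 3.71 ± 0.06, with 12 of 17 members higher and 4 lower and a median of 0.77 that turned to -0.21 on that scale (adjusted p = 0.121).

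From 12 h to 48 h 2113 genes were higher and 2255 lower in 2% glucose, of which 345 and 329 by at least 2-fold. In 0.5% glucose 2548 were higher and 2242 lower, of which 947 and 959 by at least 2-fold. Of the higher genes in 0.5% glucose 1562 turned lower on the spike-in scale, and 0 genes past the threshold turned in 2% glucose, in direction alone and with no test. Control probe sets changed as well from 12 h to 48 h. In 0.5% glucose the 3′ minus 5′ difference of ACT1 was higher at 48 h by 0.70 ± 0.03, the 3′ minus middle difference of TDH1 by 1.25 ± 0.03 and the 18S rRNA reading by 2.83 ± 0.42, and in 2% glucose these changed by 0.05 ± 0.02, -0.29 ± 0.06 and 0.53 ± 0.34. The 3′ minus 5′ difference of TDH1 changed by less, 0.209 ± 0.08 in 0.5% and -0.023 ± 0.075 in 2% glucose. The 25S rRNA reading was 10.72 at 12 h and 11.38 at 48 h in 0.5% glucose, and 10.82 and 11.04 in 2% glucose. Of 7 genes, 4 had a larger 3′ excess at 48 h by over 2 SE in 0.5% and 3 in 2% glucose, and 0 a smaller one. Arrays did not overlap for 80.4% and 88.7% of genes, where chance gives 10%. In all, 12 lists passed camera in 2% and 15 in 0.5% glucose, 8 of them in both, and the lists given here are a part of these. With an estimated correlation 0 passed in 2% and 1 in 0.5% glucose. By successive steps, 323, 48 and 138 genes changed by at least 2-fold between 12 and 18 h, 18 and 24 h and 24 and 48 h in 2% glucose, and 111, 50 and 1375 in 0.5% glucose. Adjusted over the list alone, 61 mitochondrial ribosome genes were lower in 2% glucose, and the counts of the other lists given for these comparisons were the same.

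Lists for other cell types and for the strain served as controls. Meiosis and sporulation genes, which vegetative haploid cells should lack, had adjusted p = 0.414, 0.792, 0.615 and 0.853 by camera at 12, 18, 24 and 48 h. Of the 15 members 2, 1, 4 and 6 were higher and 7, 3, 3 and 6 lower at these times. Camera tests a shift in 1 direction, so these values do not show that the members were unchanged. For alpha-specific genes the adjusted p was 0.708, 0.780, 0.253 and 0.657 by camera, with medians of 0.09, -0.01, 0.63 and -0.25. STE3, for the a-factor receptor, was 1.05 ± 0.12, 1.04 ± 0.12, 1.36 ± 0.12 and 0.74 ± 0.12 at these times, and MF(ALPHA)1 was 1.21 ± 0.15 at 24 h. At 18 h the alpha-specific genes had a mean of 0.24 and camera upward, and the auxotrophic markers had a median of -0.056, with a mean of 0.03 and camera downward. The 4 auxotrophic markers that BY4741 lacks in whole or in part had adjusted p = 0.994, 0.993, 0.801 and 0.760. URA3 had group means of 1.30 to 1.46 and MET17 of 1.85 to 2.09, below the background level of 2.29, LEU2 of 1.78 to 2.54 and HIS3 of 4.72 to 5.36.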

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

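The tests on RNA integrity, the share of poly-A RNA, the 18 h state, alpha cells and other splits of the arrays, and the counts of directions in both glucose levels and on the spike-in scale, were chosen after the results were seen, and the bounds of the tests on the 18 h state and alpha cells were changed between drafts before they were run.

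The glucose effect differed between groups of arrays, in tests of the difference itself. It differed between times for 4997 genes by the F test, and was higher at 48 h than at 12 h for 2385 genes and lower for 1968, of which 654 and 748 by at least 2-fold, with 16 lists past the threshold by camera, and 1 with an estimated correlation. Of the 2385, 1574 turned lower on the spike-in scale, and 0 of the 1968 turned higher, in direction alone. With glucose labels shuffled within each time, 1 of 100 splits, the real one, gave as many genes in each of these tests. The highest of the others was 3239 for the F test and 2962 for the difference, where the real value was 4353. Shuffled labels break the link to glucose at every time and ignore the replicate numbers. These splits therefore cannot tell a difference between times from an equal effect at all times, and chance was not excluded for that difference. For the average the real value was 4363, again 1 of 100, against 2127. For 3 arrays against 3, 10 splits are too few for a share under 0.05. Every other split also puts arrays of both real groups on each side, so differences between the real groups widen its residual spread. The low counts of the other splits are therefore no measure of false calls. The real split was the 1 with the most genes in each comparison, with 4000, 2741, 3435 and 4568 genes for the glucose levels at 12, 18, 24 and 48 h and 4368 and 4790 for 48 h against 12 h in 2% and 0.5% glucose, and the highest other split gave 0 by limma, with 886, 810, 630, 340, 713 and 293 genes at an unadjusted p under 0.05. For the successive steps the real values were 3728, 2710 and 3374 in 2% and 3277, 2655 and 4640 in 0.5% glucose, against 0, 0, 0, 1, 3 and 0 by limma and 882, 533, 363, 609, 954 and 388 unadjusted. At 12, 18 and 24 h, where the numbers paired, the 3 other splits that part every number gave 0 genes by limma, as did the 6 others, within the same unadjusted counts. The same held for the step from 12 h to 18 h in 2% glucose, where the numbers paired as well.

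Of the 4353 genes with the difference of effects past the threshold, those named by the rule for the largest changes were SRL4 (4.86), PRM5 (2.79), VBA3 (2.77, from a probe set that can be shared between related genes, which was not checked), PSK2 (2.70) and PHO92 (2.57), higher at 48 h, and ENO2 (-5.30), TKL1 (-5.28), HXK2 (-5.16), GND1 (-4.97) and ACS2 (-4.28), lower at 48 h.

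The 0.5% glucose arrays of 48 h stood apart from all others, and control probe sets outside the gene tests differed there between the glucose levels. The 3′ minus 5′ difference of ACT1 was higher by 0.657, the 3′ minus middle difference of TDH1 by 1.594, the 18S rRNA reading by 2.295 and the poly-A spike-ins by 0.490. The 3′ minus 5′ difference of TDH1 was higher by only 0.326. The 25S rRNA reading was 11.38 in 0.5% and 11.04 in 2% glucose. A lower share of poly-A RNA in total RNA would act on every gene alike. A constant shift leaves the gap between lists as it was, so it cannot alone have made 2 lists move apart. The medians of ribosome biogenesis and the TCA cycle were 1.219 and -1.261 as measured, and 0.729 and -1.751 on the spike-in scale (SE of the shift 0.165). Their gap argues against such a share as its whole cause, and the spike-in scale adds no test of this. For ribosomal protein genes, with a median of 0.114 there, it stays open whether their amount rose or that of other transcripts fell. Lower RNA integrity stays open, since 4 of 7 genes had a larger 3′ excess and 2 a smaller one, and integrity and group cannot be told apart with these counts. That restricted cultures were further along the course of 2% cultures stays open too: the 24 h to 48 h changes of both levels correlated at 0.60 across genes, past the bound set beforehand, but of 2988 genes past the threshold in both, 470 moved in opposite directions. From 12 h to 48 h, glycolysis genes were higher in 15 of 20 in 2% and lower in 17 of 20 in 0.5% glucose, the 1 list of 8 past the threshold in both that moved in opposite directions, and 2% cultures were not followed past 48 h. These 8 calls rest on the preset correlation, and with an estimated one 0 lists were called in 2% and 1 in 0.5% glucose.

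The glucose levels differed at 12 h by more genes than at 18 h or 24 h. A different share of poly-A RNA would act on every gene alike. A constant shift leaves the gap between ribosomal protein genes and other genes as it was, so it cannot alone have made that gap. The spike-in scale adds no test of this. At 12 h that scale raised every gene: the ribosomal protein median was 1.481 as measured and 1.883 on it. The median of all genes was -0.054 and 0.348 (SE of the shift 0.114). The 12 h difference did not repeat the 18 h to 48 h change in 2% glucose, with a correlation of -0.20 across genes. That 2% cultures at 12 h were short of their 18 h state stays open, since the median absolute difference of 0.5% glucose at 12 h was 0.26 from 2% at 18 h and 0.302 from 2% at 12 h, a gap smaller than the bound, with 237 against 459 genes differing by at least 2-fold. The glucose level itself may also be the cause, which was not tested apart from growth stage.

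The a-specific list was lower in 0.5% glucose at all 4 times, with 7, 7, 6 and 7 of its 7 genes lower. Cells of mating type alpha stay open: the highest mean of the alpha-specific genes in 0.5% glucose was 6.89 (SAG1), but levels of different probe sets cannot be compared. At 12 h, in 0.5% against 2% glucose, STE3 was 4.47 against 3.42 and SAG1 6.17 against 6.57, while MF(ALPHA)1 (2.24) and MF(ALPHA)2 (1.90) lay below the background of 2.29 in 0.5% glucose, and at 24 h STE3 was 5.93 against 4.57 and MF(ALPHA)1 4.74 against 3.53. Diploid cells, which would lower haploid-specific genes alike, were argued against as the whole cause at 12 h by 5 such genes, with a median of -0.371, from -1.05 (STE4) to 0.42 (NEJ1), where the a-specific median was -2.233. At 48 h these 5 genes had a median of 0.039, where the a-specific median was -2.532. They went both ways, with RME1 at -2.18 and STE4 at -0.72 lower, NEJ1 at 0.54 higher and 2 not past the threshold. That time alone decides nothing. A lower pheromone response stays open at 12 h, where pheromone-induced genes not named by the rule had a median of -0.482, between the bounds set beforehand. At 18, 24 and 48 h their medians were -0.186, -0.037 and -0.164, with 8, 5 and 8 of 16 lower and 1, 3 and 5 higher, and the group did not pass (adjusted p = 0.0628, 0.781 and 0.737). These medians and the bounds are not on the spike-in scale. The spike-ins themselves differed by -0.402, -0.16, -0.267 and 0.49 between the glucose levels at 12, 18, 24 and 48 h (SE 0.114, 0.264, 0.231 and 0.165).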

How the results depend on the processing

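The spike-in scales, the per-array one after the group-mean values had been seen, and the fits without the 48 h arrays were chosen after the data were seen, and the other settings before the data were examined.

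Over all settings, 8670 gene values kept their direction and side of the threshold, 245 lost the call, 24 gained it and 51 reversed, and for lists these were 4187, 111, 96 and 6. Apart from the spike-in scales, the estimated correlation and fry, no count moved by over 1.5 times, leaving out single arrays included. The replicate block kept 562 gene values and 231 lists, and changed only the mitochondrial ribosome list at 12 h, with an adjusted p of 0.0492 with the block in a range of 0.0268 to 0.0966 over 14 settings. Median centring kept 561 gene values and 232 lists. With quantile normalization over the tested probe sets HSP26 reversed from 12 h to 48 h in 0.5% glucose, to 0.002, and the cause was not tested.

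Camera with an estimated correlation called 0, 1, 2 and 2 lists at 12, 18, 24 and 48 h, 2 for the average, 1 for the difference of effects, and 0 and 1 for 48 h against 12 h in 2% and 0.5% glucose. The unadjusted counts were 7, 4, 4, 6, 7, 6, 1 and 5, and the preset correlation called 17, 7, 8, 16, 16, 16, 12 and 15. Fry called 27, 16, 20 and 25 lists at the 4 times, 27 for the average, 24 for the difference of effects, and 28 and 27 for 48 h against 12 h in 2% and 0.5% glucose. Fry took the direction opposite to camera for stationary phase genes at 48 h (median 0.271) and in the average (0.055), and for the glyoxylate cycle list in the average (-0.084), and the cause was not tested.

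On the scale of the spike-in group means 3776 genes were higher and 633 lower at 12 h (649 and 57 by at least 2-fold), 2802 and 579 at 18 h (21 lower by at least 2-fold), 3499 and 673 at 24 h (189 and 46), and 1055 and 3562 at 48 h (122 and 1222). With the spike-ins of each array, 195 were lower at 12 h (649 and 57 by at least 2-fold), 187 higher and 59 lower at 18 h (21 lower by at least 2-fold), 1065 and 150 at 24 h (189 and 46), and 516 higher at 48 h (122 and 1222). The construction of these scales, a constant added to every gene of a comparison, moves the counts, and the spread of the spike-ins between arrays lowers those with each array. At 18 h and 24 h that constant was within 2 SE of 0 (-0.16 ± 0.264 and -0.267 ± 0.231). Reversals at these times are thus within the spread of the spike-ins.

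On the group-mean scale the direction reversed at 12 h for SDH4 (0.154), COX9 (0.127), PRC1 (0.011), HIS3 (0.243), PCK1 (0.392), FBP1 (0.337), SDH2 (0.216), CYC1 (0.158), ADR1 (0.263), HSP12 (0.339), HSP26 (0.217), SOD2 (0.05), CTT1 (0.123), PNC1 (0.115) and ATG8 (0.377). It reversed at 18 h for ADH2 (0.026), CIT2 (0.145), SOD2 (0.12), RIM15 (0.01) and PNC1 (0.123), at 24 h for SCL1 (0.022), ADR1 (0.04), HSP12 (0.234), HSP26 (0.267), SOD2 (0.126), SCH9 (0.202) and ATG8 (0.208), and at 48 h for ADH2 (-0.103), ADR1 (-0.385), HSP12 (-0.422), RIM15 (-0.044) and GIS1 (-0.349). With the spike-ins of each array 18 of these reversed, with the same values: SDH4, COX9, PRC1, HIS3, SDH2, CYC1, ADR1, HSP26, SOD2, CTT1 and PNC1 at 12 h, ADH2 and RIM15 at 18 h, SCL1, ADR1 and SOD2 at 24 h, and ADH2 and RIM15 at 48 h.

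Without the 48 h arrays the average reversed for the TCA cycle (-0.03, test upward), glycolysis (0.092) and ergosterol (0.231), with adjusted p of 0.982, 0.182 and 0.00648 by limma's camera. Without them 1973 genes were higher and 2087 lower in the average. The call was gained by nutrient signalling and the iron regulon (adjusted p of 0.0497 and 0.0116) and lost by the respiratory chain and RNA polymerase lists (0.129 and 0.891). The cause was not tested beyond the absence of those 6 arrays. Removal of dim probe sets left too few auxotrophic markers to test, and log2 of the value plus an offset was not run, since the values were already logarithms.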

Other observations

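The tests of gene groups below were chosen after the main results were seen, 84 tests in all, 42 for 7 lists in 6 comparisons and 42 more without the genes named by the rule, adjusted apart, and the comparison given for each was picked after that too, as were the genes named here. Genes named in this section alone were not left out.

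Purine and one-carbon genes were higher in 0.5% glucose at 18 h in 13 of 15 (adjusted p = 4.09e-08, and adjusted p = 0.139 with an estimated correlation), and at 24 h in 11 of 15 (adjusted p = 0.00148, and adjusted p = 0.467 with an estimated correlation). At 48 h 13 of 15 were lower (adjusted p = 0.0012, and adjusted p = 0.467 with an estimated correlation). ADE17 was 1.48, 1.84 and -2.57 at these times. Without the genes named by the rule the adjusted p at 24 h was 0.00861, and 0.645 with an estimated correlation, so a change of the group may depend on the correlation assumed.

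Genes for daughter cell separation were lower at 48 h than at 12 h in 8 of 8 in both glucose levels, with medians of -2.06 in 2% and -2.51 in 0.5% glucose (adjusted p = 2.34e-05 and 0.00039, and adjusted p = 0.113 for both with an estimated correlation). CTS1, for the chitinase that frees daughter cells, was -1.67 in 2% and -2.35 in 0.5% glucose. Without the genes named by the rule the adjusted p in 2% glucose was 0.000686, and 0.279 with an estimated correlation, and in 0.5% glucose 0.00502, and 0.340 with an estimated correlation. Between the glucose levels at 18 h 5 of 8 were lower (adjusted p = 0.00939, and adjusted p = 0.268 with an estimated correlation). Without the genes named by the rule 3 of 6 were lower at 18 h and the list did not pass (adjusted p = 0.0558, and adjusted p = 0.603 with an estimated correlation).

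Pheromone-induced genes were lower in 14 of 18 at 12 h and 10 of 18 at 18 h (adjusted p = 0.00143 and 0.0043, and adjusted p = 0.113 for both with an estimated correlation). Without the genes named by the rule 12 of 16 at 12 h were lower (adjusted p = 0.0185, and adjusted p = 0.279 with an estimated correlation). Haploid-specific genes at 12 h were lower in 4 of 5, with a median of -0.371 (adjusted p = 0.271). That median turned higher on the spike-in scale, since the spike-ins themselves differed by -0.402 at 12 h.

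The pyrimidine group did not pass once the genes named by the rule were left out. The pentose phosphate and nitrogen groups did not pass with or without these genes. With all 11 genes, pyrimidine genes were lower in 8, 9 and 8 at 18, 24 and 48 h (adjusted p = 3.39e-05, 0.00039 and 0.0342, and adjusted p = 0.113, 0.113 and 0.401 with an estimated correlation). Without the named genes 5, 6 and 5 of 8 were lower (adjusted p = 0.0558, 0.0741 and 0.464). Pentose phosphate genes at 48 h had 0.602, with 7 of 10 lower in the full list, and nitrogen catabolite repressed genes from 12 h to 48 h in 0.5% glucose had 0.763.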
